A study of Conyza sumatrensis with 22 samples.

How the data were processed

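Leaf polyA RNA of Conyza sumatrensis (Sumatran fleabane, an annual weed) was sequenced in 22 samples from 3 populations. Per the labels, population R is resistant to the synthetic auxin herbicide 2,4-D and populations S and T are sensitive to it. Leaves were taken before spraying or 5 h after 2,4-D at 1005 g of active ingredient per hectare, which gives 6 groups of 3 or 4 samples. Each sample's population, treatment and replicate number came from its labels. The labels do not say whether the samples of a group came from separate plants, so p-values measure the spread between these samples, part of which may be technical. Untreated and treated leaves were also taken at different times, so that treatment and time of sampling coincide in all 3 populations. Time of day may differ with them, and the labels give no clock times. No group was sprayed without 2,4-D, so effects of spraying and handling coincide with those of 2,4-D as well. The comparisons of responses share these limits. With 1 resistant population, resistance and other differences between R and the sensitive populations coincide as well.

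Each sample had 1 deposited table with a line per transcript model. Per the file headers, the deposited values were estimated counts, meaning the reads assigned to each transcript, which need not be whole, together with TPM over effective transcript lengths and the effective lengths in bases. The submitters' processing notes name Trimmomatic, a read trimmer, and Salmon, which assigns reads to transcripts and splits a read that fits several. Their versions, the reference transcript set, the genome build and the strand setting are not given in the sources used here. The tables list 47916 transcript models, of which 47817 have a length that is a multiple of 3, so lengths are given as coding lengths. A read that falls on near-identical copies was divided by estimate. Between 26.1% and 41.7% of the reads of a library lay on transcripts whose estimated count was not whole within 5e-04. Values of such genes are uncertain by an amount that these shares do not give. Without a stated strand setting, a gene cannot be told from an antisense or overlapping partner.

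The transcript models carry identifiers made of a letter and a running number, and the files do not pair them with gene names. No gene name is therefore given. The lists of auxin, ethylene, abscisic acid, detoxification, stress and circadian genes and the lists of leaf cell type markers fixed before the data were examined could not be matched, and their set tests were not run. At most 2 identifiers per direction are named for each contrast. The rule, fixed before the data were examined, takes the genes with an adjusted p under 0.05 and an average log2 CPM of at least 1 that have the largest log2 fold changes. For contrasts of 2 groups it also asks that the libraries of the groups do not overlap.

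Estimated counts were rounded to whole numbers and summed over the transcripts of each gene model, giving 45437 gene models, 2232 of them with more than 1 transcript. Lines that name no gene numbered 0. A library held 19.2 M to 24.4 M assigned reads and 23073 to 24985 gene models with at least 1 count. The 10 most counted genes took 4.09% to 8.36% of a library. Counts were normalised with TMM (factors 0.837 to 1.12) and filtered with filterByExpr, which left 22627 gene models for testing and removed 22810. Tested gene models held 99.93% to 99.97% of the reads of a library. Count differences were tested with edgeR 4.0.16 in R 4.3.3 by its robust quasi-likelihood F test, in 1 model with a mean for each of the 6 groups over all 22 libraries. The common biological coefficient of variation was 0.304. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes with an adjusted p under 0.05 were called. The contrasts were the response of each population to treatment, the 3 differences between these responses and the 3 differences between untreated populations. A standard error (SE) was computed as the absolute log2 fold change divided by the square root of the F statistic. It is unreliable for genes near 0 counts. Log2 CPM values use a prior count of 2, and CPM values use the TMM-scaled library sizes.

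For a group with no count of a gene, folds are lower bounds computed against a floor of 3 counts over the group. For a group with 1 to 3 counts, the ratio is given with its exact binomial 95% counting interval. These intervals and floors cover counting error only, since reads are not independent molecules. To compare responses without choosing genes on the libraries compared, lists were also chosen in 1 population alone, with a model of that population's libraries, and measured in the other populations as mean log2 CPM per library. Differences of these means were tested with 2-sided exact permutation tests that enumerate all exchanges of libraries between populations within a treatment. These exchanges take the populations as alike in both treatments, so that differences between untreated populations enter the spread of a difference in response. Fry and camera from limma 3.58.1 were run on the same lists. This comparison of lists was not fixed before the data were examined. Overlaps of contrasts that share libraries were also counted in 20 simulations of unchanged groups, which leave out real effects.

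The procedure was tested on simulated counts drawn from the means and depths of these libraries, with genes changed 2-fold, 4-fold or 8-fold. Of 67 genes changed 4-fold, 89.6% were recovered for the response of R, 79.1% for S and 82.1% for T, with between 5 and 9 false calls. For differences between responses, 77.6% were recovered for R minus S, 80.6% for R minus T and 64.2% for S minus T. Of genes changed 2-fold, 43.3% were recovered for the response of R and 20.9% for R minus S. Simulated counts were drawn independently for each gene and library, without shifts shared by many genes of a library. Recovery and false calls in the real libraries, with edgeR or DESeq2, may therefore differ from these values. No replicates were duplicates: the lowest chi-square per degree of freedom over 30 pairs of replicates was 15.4.

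The alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter on low counts, a minimum of 1 CPM in 3 libraries, an offset for effective lengths, transcripts in place of genes, models with only the libraries of the contrast, a minimum absolute log2 fold change of 1, terms for the replicate number, and leaving out each library in turn. Removal of a trend with coding length was added after seeing the data. The TPM values entered no test.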

Results

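Leaf transcripts were measured by RNA sequencing in 3 populations of Conyza sumatrensis, 1 resistant (R) and 2 sensitive (S and T) to 2,4-D, a synthetic auxin that kills broadleaved plants. The design asks how the resistant population differs from the sensitive ones before spraying and in its response 5 h later. There were 4 untreated and 3 treated R libraries, 3 untreated and 4 treated S libraries, and 4 of each kind for T. Reads assigned per library averaged 21.6 M ± 1.9 M in untreated R (SD, n = 4) and 19.9 M ± 0.874 M in treated R (n = 3). They averaged 20.9 M ± 1.19 M in untreated S (n = 3) and 21.8 M ± 1.55 M in treated S (n = 4). In T they averaged 20.8 M ± 1.11 M untreated and 21 M ± 0.597 M treated (n = 4 each). Genes are named by the identifiers of the gene models, which the files do not pair with gene names, and what the named genes encode is therefore not given.

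The populations differed more than the treatments. The first principal component of log2 CPM, with 36.9% of the variance, set S apart from R and T, and the second, with 19.6%, set R apart from T. Within each population, treated libraries lay below untreated ones on the second component. Across genes, the median correlation of log2 CPM was 0.968 between libraries of a group and 0.94 between untreated and treated libraries of a population. Between populations it was 0.906 for R and T, 0.878 for S and T and 0.873 for R and S.

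**Figure D1:**
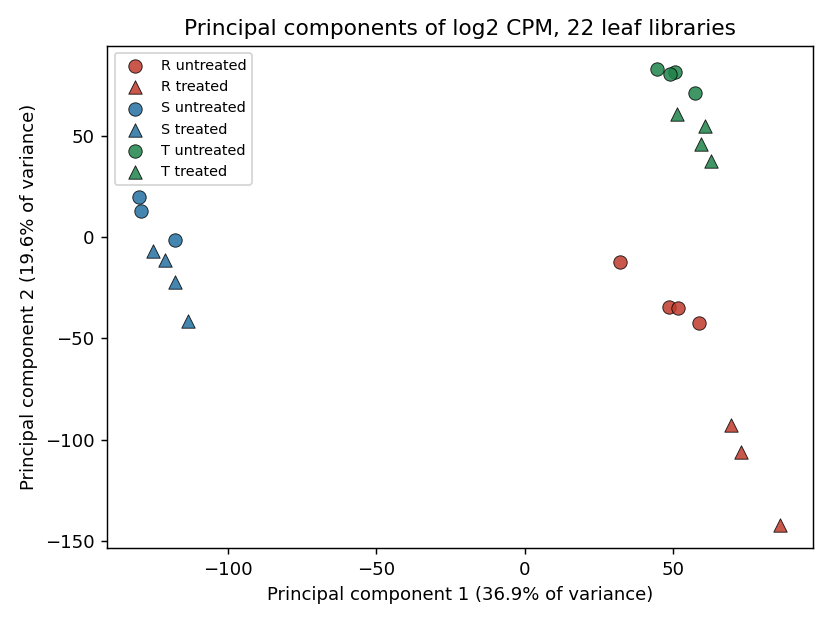
The first 2 principal components of log2 CPM (axes in component scores, with the percent of variance) are plotted for the 22 libraries, circles untreated and triangles treated, coloured by population. S libraries lie apart from R and T on the component with 36.9% of the variance, and R and T lie apart on the component with 19.6%.

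In R, 2120 genes rose and 1590 fell after 2,4-D, out of 22627 tested (edgeR quasi-likelihood test, adjusted p under 0.05). The genes that rose changed more, with a median log2 fold change of 1.89 against -0.793 for those that fell. Gene g9353 was almost without reads in untreated R, at 0.0114 ± 0.0228 CPM (SD, n = 4, 1 count in all), and reached 63.6 ± 43.4 CPM in treated R (n = 3, 3670 counts). The counting interval of this ratio was 937 to 206000 (edgeR adjusted p = 5.95e-06). Gene g25130 went from 0.0233 ± 0.0269 CPM (n = 4, 2 counts) to 82.3 ± 97.9 CPM (n = 3). Its ratio had a counting interval of 877 to 26200 (edgeR adjusted p = 5.55e-05). Both treated means leaned on library 1, at 110 CPM for g9353 against 55.6 and 24.7 in libraries 2 and 3, and at 195 CPM for g25130 against 29.4 and 22.3. In treated S and T the same genes stood at 0.186 ± 0.161 and 0.392 ± 0.509 CPM for g9353, and at 0.141 ± 0.223 and 1.33 ± 1.26 CPM for g25130 (n = 4 each). Untreated S held 0 counts of g9353, and its response was not called different between R and S (log2 difference 6.90, SE 199.36), which leaves that comparison undecided. Against T it did not pass (8.02, SE 3.63, edgeR adjusted p = 0.156). The response of g25130 passed against T (9.63, SE 2.05, edgeR adjusted p = 0.0126) and not against S (10.58, SE 4.37, edgeR adjusted p = 0.165). Among genes that fell in R, g34739 went from 2.4 ± 1.77 to 0.17 ± 0.148 CPM (log2 fold change -3.82, SE 1.23, edgeR adjusted p = 0.0384). Gene g16173 went from 3.12 ± 1.38 to 0.236 ± 0.204 CPM (log2 fold change -3.72, SE 0.80, edgeR adjusted p = 0.00336). Untreated library 4 was highest for g34739, at 5 CPM against 1.05 to 1.89. The call of g34739 held under 8 of 17 alternatives, and counts of g9353 were split between transcripts in 7 libraries. Upper-quartile factors turned the larger direction in R, with 2050 genes higher and 2124 lower. Without treated library 1 the response of R comprised 2278 genes, 1109 higher and 1169 lower, and with only the R libraries in the model it comprised 1655.

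In S, 583 genes rose and 104 fell, so that 84.9% of the called genes rose, with a median log2 fold change of 2.17 for those that rose and -1.22 for those that fell. Gene g17182 rose from 0.0153 ± 0.0266 CPM (SD, n = 3, 1 count) to 17.2 ± 19 CPM (n = 4). The ratio had a counting interval of 172 to 38000 (edgeR adjusted p = 0.00253). Gene g18889, with 0 counts in untreated S, reached 2.9 ± 2.84 CPM in treated S (n = 4), at least 54.8-fold higher (edgeR adjusted p = 0.0161). This call held under 11 of 17 alternatives. Treated library 4 was highest for both, at 43.1 CPM for g17182 against 2.27 to 19.8 and at 6.92 CPM for g18889 against 0.753 to 2.87. It stood at 105 ± 70.5 CPM in treated R (n = 3), where its log2 fold change was 6.38 (edgeR adjusted p = 0.000115). The responses of R and S at this gene did not differ by the test (edgeR adjusted p = 0.686). Gene g31219 fell from 4.51 ± 0.377 to 0.256 ± 0.385 CPM (log2 fold change -4.02, SE 0.74, edgeR adjusted p = 0.00299). Gene g15336 went from 7.48 ± 7.92 to 1.1 ± 0.417 CPM (log2 fold change -2.77, SE 0.55, edgeR adjusted p = 0.00539). Its untreated mean rested on library 3, at 16.6 CPM against 2.99 and 2.84 in libraries 1 and 2, and without library 3 the log2 fold change was -1.41 and not called. The count of 687 genes became 376 without untreated library 2, 430 without treated library 4, 219 with only the S libraries in the model and 1259 with DESeq2.

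In T, 1293 genes rose and 1145 fell, with median log2 fold changes of 1.46 and -0.8. Gene g6116 rose from 0.881 ± 0.527 to 140 ± 54.7 CPM (SD, n = 4 each; log2 fold change 7.29, SE 0.81, edgeR adjusted p = 1.53e-05). It also rose in S, from 0.699 ± 0.41 CPM (n = 3) to 239 ± 190 CPM (n = 4), and in R, where it already stood at 62 ± 41.9 CPM untreated (n = 4) and reached 284 ± 189 CPM (n = 3). The rise of g6116 was smaller in R than in S (log2 difference -6.20, edgeR adjusted p = 0.00673) and than in T (-5.10, edgeR adjusted p = 0.00854). Gene g17180 went from 0 counts in untreated T to 24.2 ± 14.9 CPM in treated T (n = 4), at least 730-fold higher (edgeR adjusted p = 0.00107). Counts of g17180 were split between transcripts in 12 libraries, as were those of g17182, and counts of g6116 in 14. Gene g71 fell from 4.46 ± 3.68 to 0.239 ± 0.285 CPM (log2 fold change -4.20, SE 0.98, edgeR adjusted p = 0.0105), with untreated library 2 at 9.66 CPM against 1.16 to 4.2 in the others. Gene g35600 went from 6.67 ± 2.63 to 0.605 ± 0.494 CPM (log2 fold change -3.44, SE 0.90, edgeR adjusted p = 0.0202). Genes that fell in T had longer coding regions (median 2067 bases, against 1404 in random lists matched on expression). Genes that rose had shorter ones (1014 against 1365). In R the differences were smaller and went the other way, with 1453.5 against 1318 for genes that rose and 1335 against 1398 for those that fell. With each library's trend on coding length removed, 1980 genes were called. Upper-quartile factors turned the larger direction in T, with 1220 genes higher and 1276 lower, as did DESeq2 with 1830 and 1890, and without treated library 1 the counts were 1621 and 1991. The call of g35600 was lost without treated library 3 (-3.32). The count of 2438 became 1113, 1364 and 1337 without untreated libraries 2, 3 and 4, 972 and 1443 without treated libraries 3 and 4, and 3720 with DESeq2.

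Relative to independent lists, the responses of the sensitive populations overlapped most. Of the genes that rose, 363 were called in both S and T, against 33.3 expected for independent lists. R shared 272 risen genes with S (54.6 expected) and 440 with T (121 expected), and 202 rose in all 3 populations. Fisher's exact tests on these overlaps gave p = 7.62e-126 for R and S and p = 7.26e-144 for R and T, with genes taken as independent, which they are not. Of the genes that fell, S and T shared 36 (5.26 expected), R and T 103 (80.5 expected) and R and S 14 (7.31 expected). Opposite directions were rare. Between R and T, 16 genes rose in R and fell in T (107 expected), and 27 fell in R and rose in T (90.9 expected). Between R and S, 5 fell in R and rose in S (41 expected). Over all tested genes, log2 fold changes of S and T had a Pearson correlation of 0.44 and a Spearman correlation of 0.38 across genes. These were 0.25 and 0.08 for R and S and 0.29 and 0.08 for R and T, and genes are not independent replicates.

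**Figure D2:**
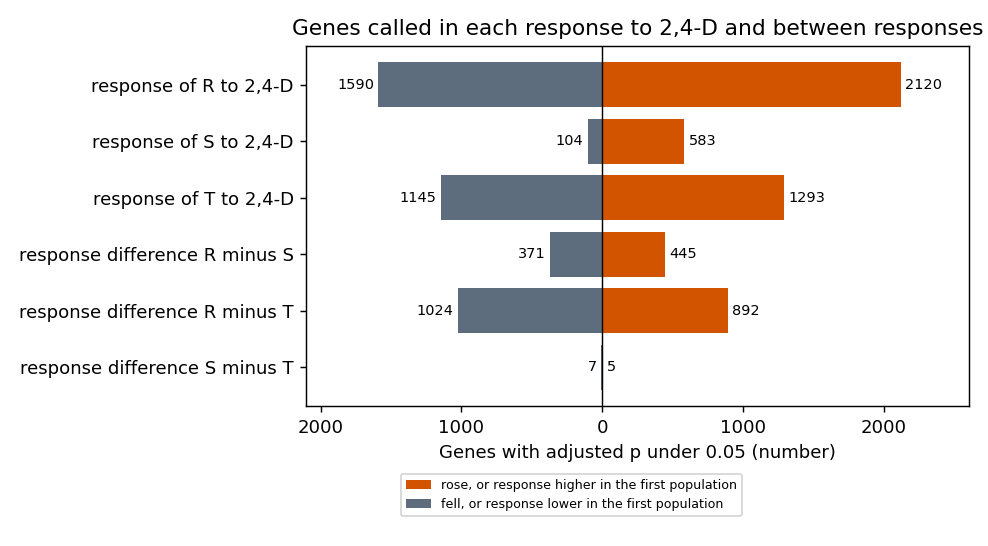
Bars show the number of genes called with an adjusted p under 0.05 (horizontal axis, genes) in the response of each population and in each difference between responses, to the right for higher and to the left for lower. R has 2120 and 1590 genes, S 583 and 104, T 1293 and 1145, and the difference between S and T has 5 and 7.

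The response of R differed from that of S at 816 genes, 445 higher and 371 lower in R, and from that of T at 1916 genes, 892 higher and 1024 lower. The responses of S and T differed from each other at 12 genes with edgeR, although 2732 had an unadjusted p under 0.05 and DESeq2 called 359. An unadjusted edgeR p under 0.05 was reached by 4907 genes for R minus S and 6428 for R minus T. The gap to S minus T was thus much smaller before adjustment than among called genes. In simulated data DESeq2 gave 36 false calls for the response of R, against 9 with edgeR. In 276 genes the response was higher in R than in both others, with median log2 fold changes of 2.23 in R, 0.0173 in S and 0.09 in T. In 182 genes it was lower in R than in both, with medians of -0.833 in R, 0.469 in S and 0.38 in T. Independent lists would share 17.5 and 16.8 genes. Simulated unchanged groups shared 0, which does not measure what shared R libraries add where both comparisons hold calls. Treated R has 3 libraries and was not divided, so part of the overlap beyond independent lists may come from the R libraries that both comparisons share. Gene g3572 stood at 0.0637 ± 0.074 CPM in untreated R (SD, n = 4) and at 54.8 ± 40.8 CPM in treated R (n = 3), while treated S held 2 counts and treated T held 0 (edgeR adjusted p of the difference 0.00381 against S and 0.0332 against T). Gene g9357 rose from 0.114 ± 0.0763 to 92.6 ± 65.9 CPM in R, against 5 counts in treated S (edgeR adjusted p = 0.0153). The log2 difference of g9357 from T was not called (8.73, SE 4.74, edgeR adjusted p = 0.231). Gene g24499 went from 0 counts to 16.8 ± 10.8 CPM in R, against 0.421 ± 0.327 CPM in treated T (n = 4, edgeR adjusted p = 0.0255). Treated S held 1.61 ± 1.69 CPM of g24499 (n = 4), and the log2 difference from S was not called (5.28, SE 4.46, edgeR adjusted p = 0.521). Treated R library 1 was highest for these genes, at 101, 168 and 29.2 CPM for g3572, g9357 and g24499, against at most 36.8, 65 and 10.9 in libraries 2 and 3. Without untreated S library 1 the log2 differences from S of g3572 and g9357 went from 12.44 and 10.16 to 10.39 and 6.05 and were not called, with 0 counts of g9357 left in untreated S. Against T, the call of g24499 was lost without untreated T library 1, which held all counts of it in untreated T (5.29, from 9.84). That of g3572 was lost without untreated R library 2 or 4, untreated T library 2 or treated T library 4 (11.92, 11.89, 9.54 and 12.26, from 12.25). Genes g9353 and g9357 have the same coding length of 1308 bases, and both had split counts in 7 libraries.

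Among genes whose response was lower in R, g34178 went from 33.9 ± 28.7 CPM in untreated R (SD, n = 4) to 24.3 ± 20.1 CPM in treated R (n = 3). In S it went from 0.964 ± 1.22 CPM (n = 3) to 81.7 ± 95.3 CPM (n = 4, edgeR adjusted p of the difference 0.0198). Treated S library 4 stood at 219 CPM, against 13.2 to 72.8 in the others, and without it the log2 difference of g34178 was -5.67, against -6.85. Gene g20155 showed the same contrast with S, from 23.5 ± 22.2 to 10 ± 7.51 CPM in R and from 0.138 ± 0.239 to 7.72 ± 7.07 CPM in S (edgeR adjusted p = 0.0316). Against T, g17180 rose less in R, from 3.61 ± 3.38 to 27.4 ± 28.2 CPM (edgeR adjusted p = 0.044). Treated T was similar, at 24.2 ± 14.9 CPM (n = 4), so this difference rested on the 0 counts in untreated T. Treated R library 1 was highest for g17180, g34178 and g20155, at 59.6, 46.5 and 18.3 CPM, against at most 15.5, 19.1 and 8.02 in libraries 2 and 3. Gene g20579 stood at 4.45 ± 8.58 and 0.0744 ± 0.0923 CPM in untreated and treated R and at 0.75 ± 1.01 and 4.95 ± 2.5 CPM in T (edgeR adjusted p of the difference 0.0431). Its untreated R mean rested on library 2, at 17.3 CPM against 0.0456, 0.0394 and 0.381 in libraries 1, 3 and 4. Without library 2 the log2 difference of g20579 was -3.81, against -8.64, and was not called. Its response was not called in R or in T (edgeR adjusted p = 0.0623 and 0.22). The calls of g17180 and g20579 against T held under 9 and 10 of 25 alternatives, and that of g20155 under 13 of 24. That of g34178 was lost without untreated S library 2 (-6.55). None of these genes was called against the other sensitive population, although the log2 differences were also negative there. Against T they were -3.66 for g34178 and -3.20 for g20155 (edgeR adjusted p = 0.083 and 0.122). Against S they were -4.83 for g17180 and -10.05 for g20579 (edgeR adjusted p = 0.0923 and 0.0779). Between S and T, the response of g42156 was higher in S, where it went from 0.0945 ± 0.0921 CPM (n = 3) to 5.26 ± 3.28 CPM (n = 4). In T it stood at 5.36 ± 0.646 and 4.47 ± 1.57 CPM (edgeR adjusted p of the difference 0.0199), a call that held under 17 of 25 alternatives. Gene g26707 was also higher in S by this test (edgeR adjusted p = 0.0448), a call that held under 7 of 25 alternatives. Genes g24578 and g29452 rose in T, by 1.88 and 2.34 on the log2 scale, and had log2 fold changes of -0.44 and -0.26 in S (edgeR adjusted p of the difference 0.00226 and 0.00507). Counts of g24578 were split in all 22 libraries.

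These counts depended on single libraries. R minus S comprised 1875, 329, 342 and 302 genes without untreated R libraries 1 to 4 and 526 without treated R library 2. It comprised 324, 380 and 1316 without untreated S libraries 1 to 3, 502 without treated S library 1, and 84 with only the libraries of R and S in the model. R minus T comprised 2975, 846 and 949 genes without untreated R libraries 1, 2 and 4, and 909 and 1187 without treated R libraries 2 and 3. It comprised 880, 933 and 911 without untreated T libraries 2, 3 and 4, and 3595, 957 and 722 without treated T libraries 1, 3 and 4. S minus T comprised 24 and 5 genes without untreated S libraries 1 and 2, 28 and 20 without treated S libraries 2 and 3. It comprised 5, 4 and 7 without untreated T libraries 2, 3 and 4, and 2 without treated T library 3. Which direction held more genes in R minus T changed with the scaling, from 892 higher and 1024 lower with TMM to 1019 higher and 783 lower with RLE factors. In R minus S it changed without treated R library 1, to 187 higher and 476 lower.

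Lists chosen in 1 population were then measured in the others, whose libraries had no part in the choice. The 205 genes that rose in the S libraries alone had a mean log2 CPM of 3.07 ± 0.2 in untreated R (SD, n = 4) and 4.69 ± 0.64 in treated R (n = 3), against 2.79 ± 0.19 and 5.44 ± 0.29 in T (n = 4 each). The mean change was 1.62 in R and 2.65 in T on the log2 scale, a difference of -1.03 (exact permutation p = 0.0184 over 2450 exchanges, 0.0384 adjusted over the 4 lists). Fry gave p = 0.00822 for the list, and camera gave p = 0.114 with an estimated correlation. Exchanging libraries between populations within a treatment carries their untreated differences into the comparison of responses, so this p and those of the other 3 lists do not measure chance for the difference in response alone. Of these genes, 78.5% had a lower log2 fold change in R than in T, and the difference was called at 55 genes lower and 2 higher in R, or 79 and 7 when adjusted over the list alone. The exact p was 0.05 without treated T library 2 and 0.0514 without treated T library 3. The 14 genes that fell in S had a mean change of -0.187 in R (exact permutation p = 0.514) and -0.888 in T on the log2 scale. The difference was 0.701 (exact permutation p = 0.0192, also 0.0384 adjusted), and camera gave p = 0.172 with an estimated correlation. The 1917 genes that rose in T rose by 0.831 in R and 0.911 in S (difference -0.0802, exact permutation p = 0.83). The 1163 genes that fell in T changed by -0.114 in R and -0.34 in S (difference 0.226, exact permutation p = 0.268).

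**Figure D3:**
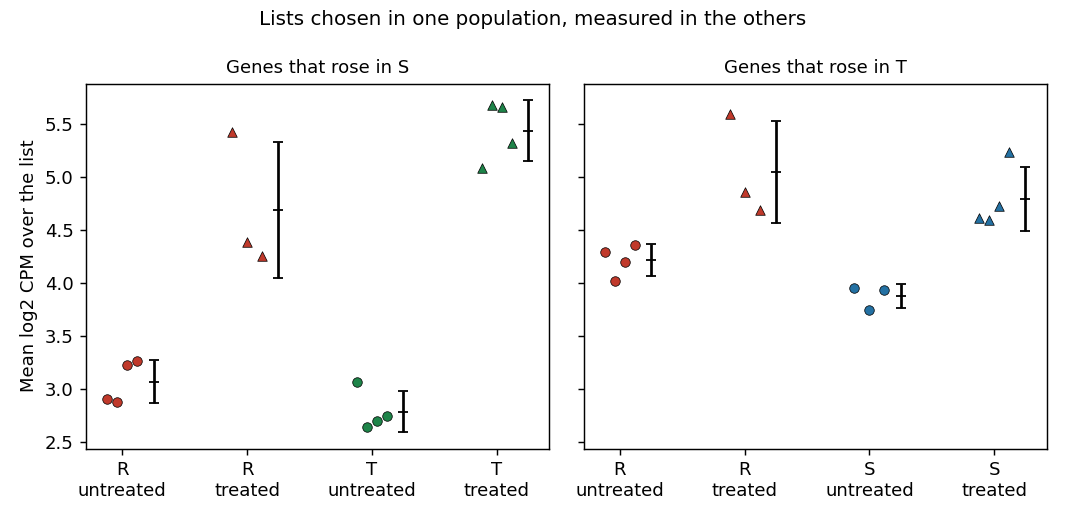
Points are libraries, with the mean log2 CPM over a list on the vertical axis, and bars beside them are the group mean and SD. For the 205 genes that rose in S, treated R averages 4.69 and treated T 5.44, and for the 1917 genes that rose in T, treated R averages 5.05 and treated S 4.79.

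Of the 363 genes that rose in both S and T, 202 were also called in R. Their median log2 fold change was 1.3 in R, 2.48 in S and 2.28 in T. The response was lower in R than in both others at 52 of them and higher in R than in both at 0, and lower than in at least 1 of them at 109 and higher at 1. These genes were chosen on the S and T libraries that enter the comparison, which favours a lower value in R.

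Before treatment, R differed from S at 6961 genes, 3767 higher and 3194 lower in R, and from T at 3332 genes, 1756 higher and 1576 lower. Populations S and T differed at 7215 genes. Genes that differed between R and both sensitive populations in the same direction numbered 1359, 764 higher and 595 lower in R. Of these, 1034 did not differ between S and T, 566 higher and 468 lower in R. Independent lists would share 292 higher and 222 lower genes. Simulated unchanged groups shared 0, which again does not measure the share owed to the same untreated R libraries. With untreated R libraries divided 2 and 2 between the comparisons, 681 to 750 genes were shared over the 6 divisions, against 226 to 306 for independent lists. The same count was 4261 genes for S against both others and 1434 for T, of which 3810 and 1086 did not differ between the other populations.

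Gene g24839 had 0 counts in untreated R, against 17.4 ± 1.35 CPM in untreated S (SD, n = 3) and 13.2 ± 0.967 CPM in untreated T (n = 4), at least 510-fold and 385-fold lower in R (edgeR adjusted p = 3.38e-11 and 4.08e-11). Treated R held 2 counts of it. Gene g687 stood at 9.13 ± 3.74 CPM in untreated R (n = 4), against 2 counts in untreated S and 0 in untreated T, at least 287-fold higher than in T (edgeR adjusted p = 4.69e-06). Gene g19162 was at least 401-fold higher in R than in T (13.5 ± 9.84 CPM, 27.1 in library 2 and 4 to 13.5 in the others, edgeR adjusted p = 5.02e-06). Gene g33817 was at least 525-fold lower in R than in T (17.9 ± 4.58 CPM in T, edgeR adjusted p = 2.67e-07). Against S, g34681 and g11185 were at least 763-fold and 548-fold higher in R, at 35.1 ± 23.3 and 26.1 ± 24 CPM (edgeR adjusted p = 8.28e-05 and 1.51e-05), the latter with 60.3 CPM in library 1 and 4.25 to 20.3 in the others. Gene g4156 stood at 29.4 ± 15.1 CPM in untreated S (n = 3), with 0 counts in untreated R and T, at least 867-fold and 903-fold higher (edgeR adjusted p = 3.03e-05 and 2.74e-05). Between S and T, g26899, at 552 ± 36.4 CPM in untreated T (n = 4) and 266 ± 43.5 CPM in untreated R, stood at 0.11 ± 0.115 CPM in S (edgeR adjusted p = 9.34e-10). Also between S and T, g40164 was at least 1590-fold lower in S (77.2 ± 8.02 CPM in T, edgeR adjusted p = 3.04e-07). Gene g44418 was at least 756-fold higher in S (24.5 ± 12.2 CPM, edgeR adjusted p = 9.61e-07).

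Some genes were without a count in every library of a population. There were 12 such genes in R that averaged at least 1 CPM in both other populations, 58 in S and 3 in T, out of 233, 378 and 179 tested genes without a count. The 3 counts taken as a floor correspond to 0.0205 CPM over the R libraries, 0.02 over S and 0.018 over T. Reads of all 3 populations were assigned to the same transcript models, whose origin is not given. Counts alone therefore do not tell a gene without expression from one whose reads did not match its model. The large folds between untreated populations carry the same limit.

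**Figure D4:**
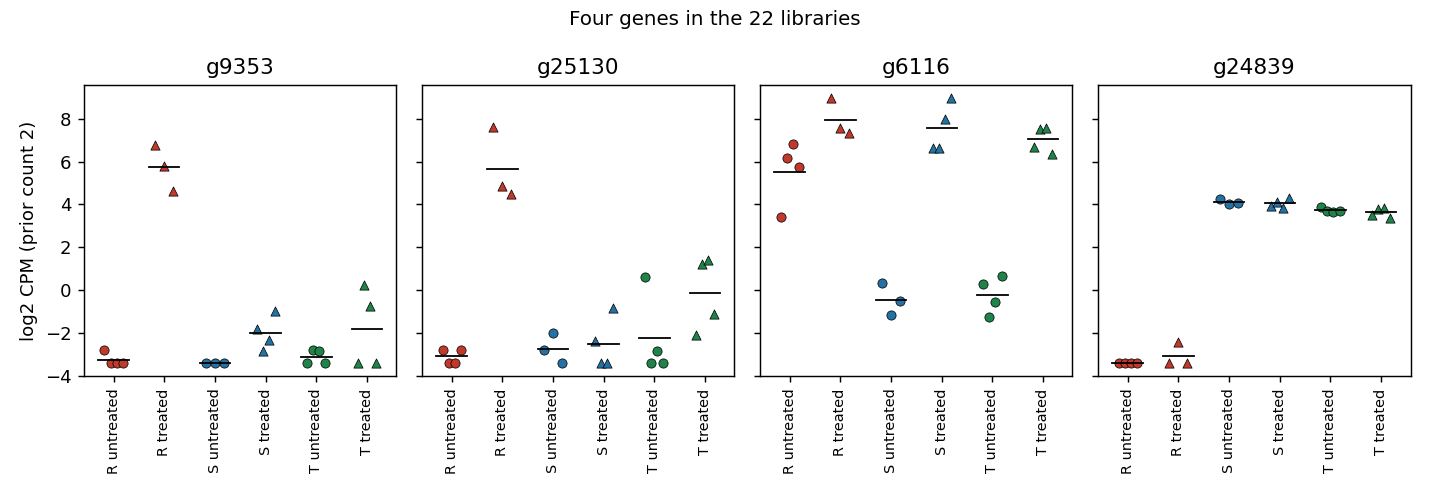
Points are libraries and horizontal lines group means of log2 CPM (vertical axis, prior count 2) for g9353, g25130, g6116 and g24839 in the 6 groups. The lowest values mark libraries with 0 counts, and g24839 lies there in all 4 untreated R libraries, while S and T average 17.4 and 13.2 CPM untreated.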

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

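The direct tests of differences between responses, the counts over other divisions of the libraries and the comparison of a list from T matched in size were set before their results were seen. The comparison of lists chosen in 1 population and the tests of precision, single libraries, overall divergence, untreated level and coding length were chosen afterwards.

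Differences between responses were tested directly. The response of R differed from that of S at 816 genes and from that of T at 1916, and the responses of S and T differed at 12. Fitted differences were 12.44 against S and 12.25 against T for g3572, 10.16 against S for g9357, -6.92 and -6.85 against S for g20155 and g34178, and 9.84, -9.09 and -8.64 against T for g24499, g17180 and g20579. Between S and T they were 5.94, 4.92, -2.61 and -2.32 for g42156, g26707, g29452 and g24578. All are log2 values, and those of genes near 0 counts in a group depend on the prior count and are no bounds. The list that rose in S differed between R and T by -1.03, and the list of 14 genes that fell in S by 0.701. Neither passed in camera with an estimated correlation (p = 0.114 and 0.172).

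The response of R differs from those of S and T at more genes than those of S and T from each other. By an unadjusted edgeR p under 0.05 the gap was much smaller, with 4907 genes for R minus S, 6428 for R minus T and 2732 for S minus T. The counts of called genes therefore overstate how alike S and T were. The median standard error for S minus T was 0.965 times the larger of the other 2, which argues against lower precision as the whole cause. In simulated data 64.2% of 4-fold differences were recovered for S minus T, against 77.6% and 80.6% for R minus S and R minus T. Recovery was closer at 2-fold (20.9% against 20.9% and 22.4%) and at 8-fold (84.8% against 86.4% and 89.4%). Different genes were changed in the simulation for S minus T, so these values do not show a loss of power, and some loss stays open. The lowest count for R without any 1 library was 302, above the highest for S minus T, 28, and the pair that differed most when untreated, S and T with 7215 genes, had the fewest differences between responses, 12. These counts argue against a single library and overall divergence as causes, and a biological difference between the populations remains a hypothesis. Chance, resistance itself, other traits of R and different courses over the day in R stay open and cannot be separated here, with 1 resistant population and 1 time after spraying.

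Genes that rose in S had a smaller mean rise in R than in T by the exchange of libraries (-1.03), a call lost in camera with an estimated correlation (p = 0.114), so that the pattern itself is uncertain. The difference nearest to 0 without any 1 library was -0.815, without treated R library 3, against -1.03 with all libraries, so 1 library does not account for its size. A higher untreated level in R may contribute: untreated R minus T was 0.283 (exact permutation p = 0.114, 0.228 adjusted over the 4 lists) and treated R minus T was -0.749 on the log2 scale (exact permutation p = 0.143, 0.286 adjusted), and neither value decides. A lower response of R at any list of genes that rise in a sensitive population cannot be told apart either: the 205 genes with the lowest p in T, 101 of them also in the list from S, differed by -0.794 between R and S (exact permutation p = 0.0996), while the whole list of 1917 genes that rose in T differed by -0.0802 (exact permutation p = 0.83), which goes against it for that list. Resistance of R stays open as an untested biological explanation.

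Genes that fell in T have longer coding regions than other genes. Among 5963 genes with p over 0.2 in both R and S, chosen without T, long minus short genes shifted by -0.43 between untreated and treated T (exact permutation p = 0.0286, the smallest that these 70 exchanges can give, 0.0686 adjusted over 12 such tests), close to the -0.413 over all genes. A trend with coding length over whole T libraries, such as RNA quality or library preparation can give, may underlie this. A response of many genes in T may do so as well. Over the same 19297 genes as the -0.413 in T, the shift was 0.0692 in R (exact permutation p = 0.4) and -0.00498 in S. The genes called in T shifted by -1.51 in T, -0.404 in R and -0.634 in S (exact permutation p = 0.0286 each, 0.0686 adjusted). Those genes were chosen by their calls in T, where long ones fell and short ones rose. Any response shared with R or S then gives such shifts, so these values do not separate the explanations. As the whole cause of the T calls the trend is argued against by the 71.9% of them that stayed in the same direction with the trend removed. A first version of the test, over genes with p over 0.2 in T, gave -0.0619 and is void because those genes were chosen for a small change.

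Other divisions of the same libraries were refitted, the real one counted. For S, 1 of 35 divisions called as many genes as the real 687 (highest other 303), and for T 1 of 35 (2438, highest other 14). For untreated R against S it was 1 of 35 (6961, highest other 3170). For untreated R against T it was 1 of 35 (3332, highest other 2), and for untreated S against T 1 of 35 (7215, highest other 1060). This share of 0.0286 is the smallest that 35 divisions can give, and it was not adjusted over the results tested. It argues against chance for these without excluding it, and the samples exchanged may not be separate plants. For R, 2 of 35 divisions called as many genes as the real 3710, so chance stays open for it. The other one, with 3868 genes, put untreated library 1 with the 3 treated libraries. Of 100 drawn relabellings, 2 gave as many genes as R against both untreated (1034, highest other 1484), the real one included. The other one put the 3 S libraries in the place of R. These exchanges take all 3 untreated populations as alike. A low share therefore speaks only against that and decides nothing particular to R. The same count was 3810 genes for S and 1086 for T. Of 100 relabellings each, 4 called as many genes as R minus S (816, highest other 3027), 3 as R minus T (1916, highest other 5038) and 6 as S minus T (12, highest other 8098). For each of these, the relabelling with the highest count moved untreated libraries between populations, which carries the untreated differences between populations into the comparison of responses. These relabellings, like the exchanges behind the exact tests of the lists, are therefore no fair measure of chance for the differences between responses, and chance is left open for R minus S and R minus T and was not excluded for S minus T.

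Libraries far from the others of their group of 4 were found in 13 of 87 tests, each of 1 measure, list or named gene in 1 group. The tests used the same libraries repeatedly and are not independent. Chance gives about 1 in 20, a rate that does not hold where 3 libraries tie at 0 counts, as for g9353 in untreated R, g9357 in treated S and g3572 and g24499 in untreated T, so that a few reads in 1 library set it apart. The values are log2 CPM. They were -2.83 for g9353, 2.4 for g16173 and -3.4 for g9357 in untreated R libraries 1, 4 and 1. In treated S they were -1.37 for g9357 and a mean of 3.84 over the genes that fell in T, both in library 4, and -0.59 for g42156 and -0.69 for g26707, both in library 2. In untreated T they were 1.54 for g35600, -0.66 for g24499 and 3.88 for g24839 in library 1, and -2.09 for g3572 and 4.42 for g24578 in library 2. In treated T library 3, g26707 stood at 1.28.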

How the results depend on the processing

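Removal of the coding-length trend and the alternatives for the lists chosen in S and T were chosen after seeing the data. All counts below use an adjusted p under 0.05, and the cause of a change was not tested unless given. With a minimum absolute log2 fold change of 1, which by construction removes genes, the counts were 2151 for R, 1297 for T, 4233, 2074 and 4274 for untreated R against S, R against T and S against T, and 632 for R against both untreated. DESeq2 called 1259 genes for S, 3720 for T, 1846 for R minus S, 3401 for R minus T and 359 for S minus T. It also gave more false calls than edgeR in simulated data for the response of R, 36 against 9. Without a filter on low counts R minus S comprised 503 genes. With only the libraries of the contrast, which leaves fewer samples, the counts were 1655 for R, 219 for S, 84 for R minus S and 1 for S minus T.

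The replicate numbers gave no sign of pairing samples within a population: correlations of deviations between the 10 pairs of the same number and population were -0.406 to 0.0386, 0 of them above 0.1. Between populations, those of 41 pairs of the same number were -0.423 to 0.344, 14 of them above 0.1. Within populations, 1 of 20 libraries correlated best with its own number. The number as a replicate block gave 217 genes for R minus S, 901 for R minus T and 3 for S minus T. Population and number together as the block gave 1397 for R, 196 for S, 1144 for T, 80 for R minus S, 107 for R minus T and 1 for S minus T. The block by number changed no other count by over 1.5 times.

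Without 1 library each, the counts were 2278 (treated R 1) to 4555 (untreated R 1) for R, 376 (untreated S 2) to 852 (treated S 2) for S, 972 (treated T 3) to 3612 (treated T 1) for T, 302 (untreated R 4) to 1875 (untreated R 1) for R minus S, 722 (treated T 4) to 3595 (treated T 1) for R minus T and 2 (treated T 3) to 28 (treated S 2) for S minus T. The counts for untreated populations and for R against both stayed within 1.5 times. The difference for the list that rose in S was -1.4 to -0.815, with an exact permutation p of 0.05 and 0.0514 without treated T libraries 2 and 3 (-0.96 and -0.962), and that for the list that rose in T was -0.356 to 0.0978, never past the threshold. The values for the latter changed sign without treated R libraries 2 and 3 and treated S library 4 (0.0154, 0.0978 and 0.0674).

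RLE and upper-quartile factors, effective lengths, the CPM filter and transcripts moved no count by over 1.5 times, and neither did removal of the coding-length trend (1980 for T, 1459 for R minus T). Of 700 combinations of a named gene and an alternative, 591 kept the call, 109 lost it and 0 changed direction. Set tests of the pathway and marker lists were not run. In simulated data of this depth, 20.9% of 2-fold differences between the responses of R and S were recovered.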

Other observations

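The tests in this part were chosen after seeing the data.

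Genes with neighbouring running numbers were called together in the same direction more often than in shuffles, except for S minus T. The ratio to the shuffled mean tended to fall with the number of genes called, so it does not compare responses with untreated populations. It was 4.37 for S with 687 genes and 1.12 for untreated S against T with 7215. At closer numbers it was 1.85 for R with 3710 genes and 1.42 for untreated R against T with 3332. In R, 396 of 15611 pairs of tested genes with consecutive numbers were both called in the same direction, against a mean of 214 over 10000 shuffles (permutation p = 1e-04, the smallest the shuffles can give, 2e-04 adjusted over 18 tests). The pairs numbered 47 against 10.8 in S and 199 against 90.8 in T, 38 against 10.3 for R minus S and 116 against 56.2 for R minus T. They numbered 847 against 743 for untreated R against S, 241 against 170 for R against T and 888 against 796 for S against T, and 0 for S minus T. Whole counts in every library show no split in the estimates, but not that each read fitted a single gene. Among genes with such counts, the pairs numbered 92 against 56.6 in R, 9 against 2.55 in S (highest shuffle 10) and 56 against 22.7 in T. They numbered 8 against 2.58 for R minus S (highest shuffle 11), 25 against 13.5 for R minus T and 0 for S minus T, and were 1.12, 1.43 and 1.16 times the shuffled mean for untreated R against S, R against T and S against T. Whether consecutive numbers mark neighbouring genes is not given in the sources used here.

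Libraries of a group took different positions between the untreated and treated means of their population. Over genes called without the library itself, and with 0 for the mean of the other untreated libraries and 1 for that of the treated ones, untreated R library 1 had a median position of 0.458, and untreated R libraries 2, 3 and 4 had -0.168, 0.0471 and 0.0311. Treated T library 1 lay at 0.469, and treated T libraries 2, 3 and 4 at 0.845, 1.19 and 0.939. Treated S library 4 lay at 1.4, and treated S libraries 1, 2 and 3 at 0.718, 0.691 and 0.949. Leaving out untreated R library 1 raised the count for R to 4555, and leaving out treated T library 1 raised that for T to 3612.

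The genes without a count in a population included g30305 and g30306 in R, with consecutive numbers, at 2.15 and 3.49 CPM in S and 3.29 and 4.16 CPM in T. They were chosen after their values were seen.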
